A study of Arabidopsis thaliana with 2 samples.

How the data were processed

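Small RNAs were sequenced by Solexa from rosette leaves of 35-day-old wild-type Arabidopsis thaliana plants of the Columbia-0 ecotype, grown with a 16 h day at 22 °C. Per the labels, 1 RNA isolation was sequenced in 2 independent runs, so the 2 libraries were taken as technical replicates of 1 group and n = 2 counts libraries, not plants; whether both hold that RNA was not tested. Per the labels' protocols, 35 µg of RNA per sample went to a sequencing centre, which built the cDNA libraries by its own procedure. The adapter trimming, base calling and any filters are not given in the sources used here.

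The deposited values are whole-number counts per distinct sequence tag, with no normalization and no coordinates. Tested on the files, every listed tag was 18 to 24 nt long and had at least 5 counts. A tag that is not listed can therefore have had 0 to 4 counts, and the sum of a file is the total of its listed tags, not the depth of sequencing. Library 1 held 1595539 counts over 41829 tags and library 2 held 6230933 counts over 167616 tags. The denominator of the size shares was planned as all tags of 18 to 28 nt and is here 18 to 24 nt, the lengths present.

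Each tag was matched over its full length to both strands of TAIR10.1, the nuclear, plastid and mitochondrial genome of the ecotype, and all coordinates are 1-based positions from that matching. Exact matches were found with a seed of 18 nt, and matches with up to 1 mismatch with bwa 0.7.19-r1273. A tag was given to 1 annotation class by its matches, in the order rRNA, tRNA, snRNA or snoRNA, MIRNA gene, TAS locus, plastid, mitochondrion, protein-coding gene in sense, protein-coding gene in antisense, other annotated gene and intergenic. The nuclear 25S rRNA lies 3' of the 5.8S genes and has no gene in this annotation, so an alternative counted the 4 kb 3' of 5.8S as rRNA. A tag was called adapter-like when it matched no genomic site and shared at least 16 nt with the 26-nt 5' adapter of the Solexa small RNA kit, with at most 2 mismatches.

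A list of 73 mature miRNAs grouped by target and a list of 8 TAS loci were fixed before the data were examined, as were the tests, the alternative settings and the rule for named genes. All 73 listed sequences matched an annotated mature product of their family. Differences between the libraries were tested per miRNA with an exact conditional binomial test, two-sided, given each library's total of listed miRNA counts, with Benjamini-Hochberg adjustment over the miRNAs with at least 10 counts summed. A call needed an adjusted p of 0.05 or less and a ratio of shares of at least 1.5. A miRNA unlisted in 1 library was given 4 counts there, the most it can have had. It was left untested where this put that library level with or above the other. Its ratio is the lowest that the counts allow, and this bound has counting error of its own. The allowance was chosen after the files had been seen. It departs from the test as first written, which made no allowance for unlisted tags. Poisson counts were simulated for the 73 miRNAs in 20 draws with both libraries' totals. Over all draws, 0.489% of 818 tests of unchanged miRNAs gave a call. The calls were 66.5% of 155 tests at a 2-fold change and 88.2% of 161 at a 4-fold change. These rates hold for counting error alone and do not give the rate of false calls between the real libraries.

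Shares carry 95% Wilson intervals, and ratios carry exact conditional intervals. These cover counting error only, since the reads have no molecular identifiers. A test on the reads of 2 libraries compares those libraries and not conditions, and its p-values leave out every other source of technical variation. Phasing at a TAS locus was the share of 21-nt reads in the fullest of 21 registers, antisense reads shifted by 2 nt, against 10000 random draws of registers for the same tags, where a library had at least 20 such reads. The pericentromere was taken as the 3 Mb on each side of the midpoint of the 1-Mb window with the fewest protein-coding genes. Such a midpoint marks low gene density and need not be the position of the centromere. Only tags of 24 nt with 1 match entered the density.

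The text names the 20 listed miRNAs with the highest mean share, the 5 called miRNAs with the largest ratio in each direction, every TAS locus, the 10 most abundant tags, the 10 protein-coding genes with the most uniquely matching reads of 20 to 25 nt and at least 10 reads per library, and each target group with some members. Alternatives changed the counting of tags, the rRNA and tRNA content, the scaling, the count minimum, the treatment of isomiRs (tags whose ends lie up to 2 nt from the mature ones) and the handling of tags with several matches. Library 2 was also thinned at random, in 2 draws that share no read, until the tags left at 5 or more counts summed to the total of library 1. Sequences of tags without a genomic match are not printed. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.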

Results

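The data were 2 small RNA libraries of wild-type rosette leaves, made from 1 RNA isolation per the labels, so the comparison they allow is between 2 sequencings. Whether both hold that RNA was not tested, and the ratios and SDs below could include a difference between RNAs. Library 1 listed 1595539 counts and library 2 listed 6230933. The libraries had 8995 tags in common, which held 65.5% of the counts of library 1 and 39.2% of those of library 2. Across these shared tags the log10 counts had a Pearson r of 0.229 and a Spearman rho of 0.136; tags are not independent replicates.

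The first comparison was of the size classes, in which plant miRNAs and trans-acting siRNAs are mostly 21 nt long and the siRNAs that direct DNA methylation are mostly 24 nt long. The 21-nt class took 35.6% (95% Wilson interval 35.5 to 35.7) of library 1 and 35.2% (35.2 to 35.3) of library 2, a mean of 35.4% ± 0.264 (SD, n = 2 libraries). Which library was higher, and by how much, depended on the tags counted: without tags that match rRNA (the stretch 3' of 5.8S included) or tRNA it was 55.6% against 37.7%, among tags that match the genome 36.2% against 38.0%, and with library 2 thinned to the total of library 1 35.6% against 39.1%. The 24-nt class held 15.3% (15.3 to 15.4) of library 1 and 35.3% (35.2 to 35.3) of library 2, a mean of 25.3% ± 14.1 (SD, n = 2). Library 1 had more of every other length, for example 7.79% against 3.92% at 18 nt and 12.4% against 8.42% at 23 nt. Counted once per distinct tag, the 24-nt class was 32.5% of library 1 and 60.0% of library 2.

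**Figure D1:**
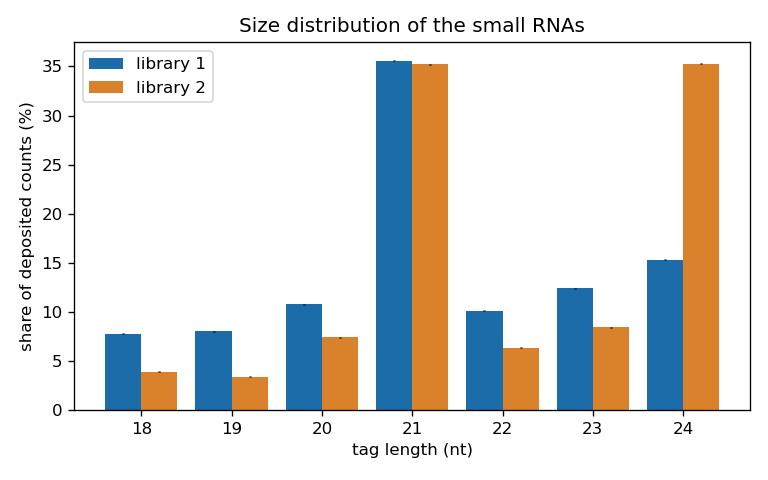
Share of deposited counts (%, vertical axis) by tag length (nt, horizontal axis) in library 1 and library 2; error bars are 95% Wilson intervals of the counting error. Both libraries peak near 35% at 21 nt, and library 2 has a peak of 35.3% at 24 nt where library 1 has 15.3%.

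Among 24-nt reads, 46.9% (46.7 to 47.1) of library 1 and 70.2% (70.2 to 70.3) of library 2 began with A, the 5' base preferred by the Argonaute protein AGO4. Among 21-nt reads, 72.0% (71.9 to 72.1) and 81.0% (81.0 to 81.1) began with T, the base preferred by AGO1. The means were 58.6% ± 16.5 and 76.5% ± 6.39 (SD, n = 2). Without tags that match rRNA or tRNA the T share was 81.5% in library 1 and 83.0% in library 2, and counted once per distinct tag 27.5% and 37.5%. The A share of 24-nt reads was 54.6% and 71.2% without tags that match rRNA or tRNA, and 59.7% and 69.8% once per distinct tag.

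Perfect matches to TAIR10.1 covered 88.5% (88.5 to 88.6) of the counts of library 1 and 68.6% (68.6 to 68.6) of those of library 2, a mean of 78.6% ± 14.1 (SD, n = 2). MIRNA genes gave 23.1% and 24.8%, but 65.8% and 20.6% among tags with 1 match, and TAS loci gave 1.69% and 2.04%, or 5.74% and 8.13% among those tags. Fragments of the translation machinery were higher in library 1, with 24.2% against 5.81% from annotated rRNA and 7.30% against 2.03% from tRNA. Intergenic sequence was higher in library 2, 18.9% against 6.84%, and 85.2% of its intergenic counts were 24 nt long with the stretch 3' of 5.8S set apart. With that stretch counted as rRNA, rRNA held 42.2% of library 1 and 8.24% of library 2, and the class of other annotated genes fell from 20.2% to 3.63% in library 1 and from 6.48% to 4.47% in library 2. Among tags with 1 match, which leaves out repeated genes, rRNA was 0.868% and 0.0949%, tRNA 1.81% and 0.561% and intergenic sequence 15.4% and 55.9%. Protein-coding genes gave 2.45% and 3.88% in sense and 1.15% and 2.28% in antisense, or 1.23% and 3.54% in antisense among tags with 1 match. Outside rRNA and tRNA, which were counted first, the plastid gave 1.46% and 2.04%, turned to 3.12% and 1.26% among tags with 1 match. The mitochondrion, also without its rRNA and tRNA, gave 0.0698% and 0.305%, turned to 0.367% and 0.171% with each tag split evenly over its matches. Plastid rRNA was higher in library 1, for example 6.57% against 0.0857% from 4.5S and 4.01% against 0.161% from 23S. The snRNA and snoRNA genes gave 0.0344% and 0.00823%.

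**Figure D2:**
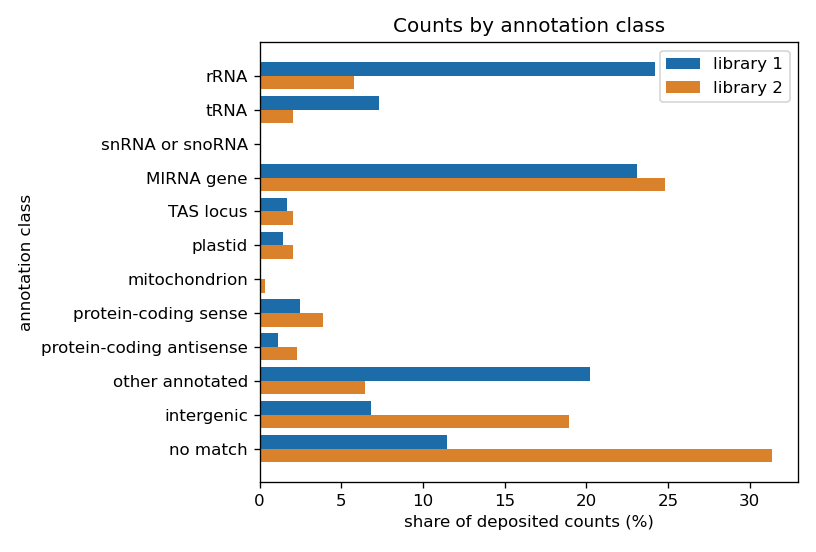
Share of deposited counts (%, horizontal axis) in each annotation class (vertical axis) for library 1 and library 2, each tag counted in 1 class. MIRNA genes are near 24% in both libraries, rRNA is 24.2% in library 1 and 5.81% in library 2, and tags with no match are 11.5% and 31.4%.

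The second comparison asked how far the 2 libraries give the same miRNA profile. The profiles differed: by exact mature sequences library 1 was led by miR159a, which targets GAMYB-like MYB transcription factors, miR161.1, which targets pentatricopeptide repeat (PPR) genes, and miR168a, which targets AGO1. Library 2 was led by miR167a, which targets auxin response factors, and by miR157a and miR156a, which target SPL transcription factors of the juvenile-to-adult transition. With isomiRs, tags whose ends lie up to 2 nt from the mature ones, miR161.1 led library 1, with 170454 counts against 89982 for miR159a. The 3 most abundant miRNAs held 78.2% of the listed miRNA counts in library 1 and 87.9% in library 2. Of 73 listed miRNAs, 41 were present in library 1, 55 in library 2 and 37 in both. The exact conditional binomial test called 44 of 52 tested miRNAs, 21 higher in library 1 and 23 higher in library 2, and the largest adjusted p among them was 0.00243.

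In shares of the listed miRNA counts, miR159a (chromosome 1, 27713234 to 27713254) held 39.5% of library 1 and 0.468% of library 2, a ratio of 84.4 (82.2 to 86.6). Its relative miR159b was 64.8-fold higher in library 1. MiR161.1 (chromosome 1, 17825731 to 17825751) was 234-fold higher in library 1, but 19.2-fold once its isomiRs were added, and miR168a (chromosome 4, 10578652 to 10578672) was 160-fold higher. Among the miRNAs listed in both libraries, miR846 had the largest ratio in this direction, 462 (291 to 782), from 1448 and 18 counts. MiR319a, which targets TCP factors, had 52 counts in library 1 and was unlisted in library 2, at least 74.7-fold higher (27.5 to 284). MiR167d was 26.2-fold and miR396b 4.25-fold higher in library 1. Adding isomiRs brought miR846 to 19.6-fold, no longer the largest, miR168a to 79.3-fold and miR167d to 10.2-fold.

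In the other direction, miR157a (chromosome 1, 24913276 to 24913296) held 0.653% of library 1 and 40.2% of library 2, 61.5-fold higher in library 2. MiR167a (chromosome 3, 8108090 to 8108110) held 3.63% and 42.3%, 11.6-fold higher. MiR173, which triggers phased siRNAs at TAS1 and TAS2, was unlisted in library 1 and had 7602 counts in library 2. It was at least 331-fold higher (129 to 1214). MiR164a, which targets NAC factors, was 51.9-fold higher in library 2, miR822 34.5-fold and miR157d 32.6-fold. MiR166a and miR165a, which target class III HD-ZIP factors of leaf polarity, were 17.7-fold and 15.3-fold higher, miR396a 12.8-fold, miR156a 9.87-fold, miR172a 8.45-fold, miR158a 3.10-fold and miR391 1.89-fold higher. With isomiRs, miR156a was 20.4-fold, miR166a 28.2-fold, miR165a 23.9-fold, miR396a 5.37-fold and miR391 2.89-fold higher in library 2.

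**Figure D3:**
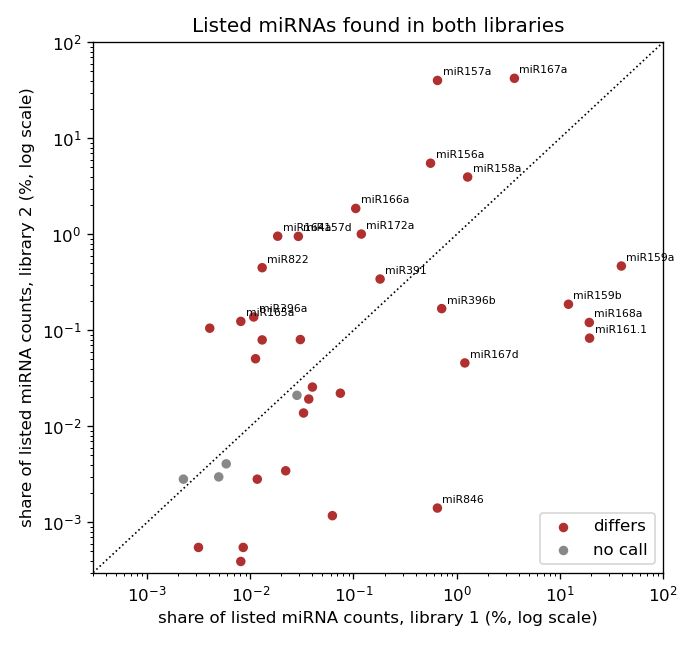
Share of listed miRNA counts in library 1 (%, log scale, horizontal axis) against library 2 (%, log scale, vertical axis) for the 37 listed miRNAs present in both; red points differ by the exact test, grey points do not, and the dotted line marks equal shares. MiR159a and miR161.1 lie far below the line and miR157a and miR167a far above it.

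Across the 37 shared miRNAs the log10 shares had a Pearson r of 0.490 (95% bootstrap interval 0.286 to 0.679) and a Spearman rho of 0.530; miRNAs are not independent replicates. The chi-square over its degrees of freedom was 22221, where counting error alone gives about 1. Scaled by that dispersion, 0 miRNAs were called and 1 had an unadjusted p under 0.05. The dispersion was estimated from the same differences between the libraries, so this cannot show whether the calls hold. Scaling by all deposited counts moved every log2 ratio by -0.56 and median-of-ratios scaling by -0.52, relative to scaling by the listed total. The listed miRNAs were 13.9% (13.9 to 14.0) of the counts of library 1 and 20.5% (20.5 to 20.5) of library 2, a mean of 17.2% ± 4.64 (SD, n = 2), and with isomiRs they were 22.6% and 23.9%.

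The sequences annotated to the 2 arms of 1 hairpin could be compared at 16 hairpins, a comparison chosen after the values were seen. The count of an arm was that of its sequence, which several MIRNA genes can share, 7 for miR166a and 3 for miR157a. A pair of values therefore need not come from 1 hairpin alone. For MIR168a the 5' arm, whose sequence 2 MIRNA genes share, had a log2 ratio of library 1 over library 2 of 6.76. The 3' arm had -1.88, both in shares of all deposited counts. For MIR396a the values were -4.23 and 2.55, and for MIR390a, whose 5' sequence 2 MIRNA genes share, -3.17 and 2.46. The arms differed by over 1 log2 unit at 12 of the 16 hairpins.

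**Figure D4:**
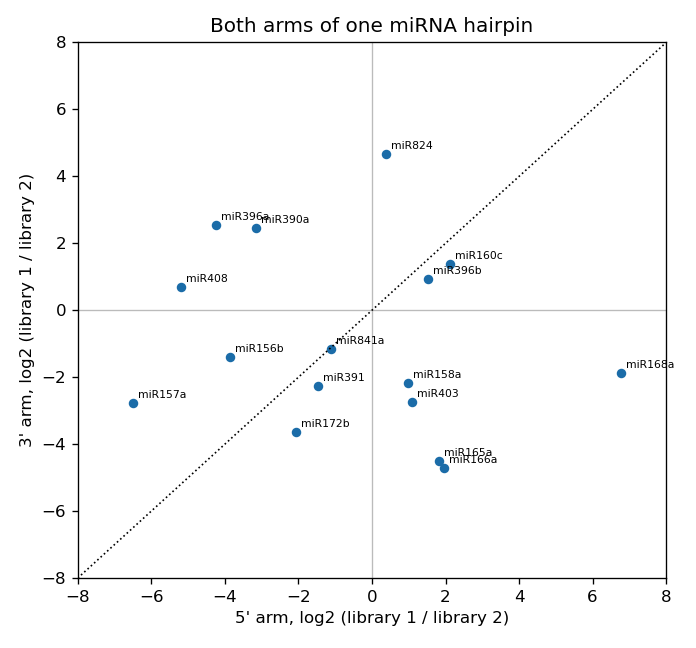
Log2 ratio of library 1 over library 2, in shares of all deposited counts, of the 5' arm (horizontal axis) and the 3' arm (vertical axis) of 16 miRNA hairpins with both arms listed in both libraries; the dotted line marks equal ratios. MIR168a lies at 6.76 and -1.88, and 12 hairpins lie over 1 log2 unit from the line. An arm's count is that of its sequence, which more than 1 MIRNA gene can share.

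By target group, miRNAs against transcription factors held 58.8% of the listed counts in library 1 and 94.0% in library 2, and 37.4% and 92.0% with isomiRs. Of 26 tested, 9 were higher in library 1, 12 higher in library 2 and 5 were not called, and 21 passed when adjusted over the list alone. Scaling by all deposited counts or by median of ratios gave 8 and 13, since miR824, which targets AGL16, was no longer called and miR156h was called; with isomiRs miR824 was not called either. In the silencing group, miR168a was higher in library 1 while miR162a (DCL1) and miR403 (AGO2) were 2.62-fold and 4.50-fold higher in library 2, miR403 7.52-fold with isomiRs, and all 3 passed adjusted over the list alone. Both triggers of trans-acting siRNAs were higher in library 2, miR390a by 6.10-fold, and both passed adjusted over the list alone. Of the PPR group, miR161.1 was higher in library 1 and miR161.2 was at least 24.8-fold (9.65 to 91.5) higher in library 2. MiR400 was not called, and 2 of the group passed adjusted over the list alone. All 3 tested copper miRNAs were higher in library 1, and 3 passed adjusted over the list alone. The ratios were at least 71.8-fold (26.4 to 274) for miR398b, 15.6-fold for miR397b and 2.38-fold for miR408. With isomiRs miR408 was 1.61-fold higher. The listed miR408 is the 3' arm, and the 5' arm went the other way, with 17 counts in library 1 and 2433 in library 2. MiR397a and miR857, not tested, had 8 counts each in library 2 and were unlisted in library 1. The sulfate miRNA miR395a was 5.75-fold higher in library 1, from 7 counts in each, and was the 1 tested and the 1 passing adjusted over the list alone. The phosphate miRNA miR827 was not called, with 11 and 38 counts, and 0 passed adjusted over the list alone. Of 13 tested young miRNAs, which are found in few plant lineages, 6 were higher in each library, among them miR846 and miR850 in library 1 and miR822 and miR163 in library 2, and 12 passed adjusted over the list alone. Under both other scalings library 1 had 5, since miR823 was no longer called. Neither F-box miRNA could be tested; miR394a had 6 counts in library 2 and miR393a was listed in neither library.

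The third comparison was of the TAS loci, noncoding transcripts that are cut by a miRNA and processed into siRNAs in 21-nt steps. TAS1A (AT2G27400) and TAS3A (AT3G17185) had 454 and 165 CPM (counts per 1000000 deposited counts) in library 1 and 8041 and 3438 CPM in library 2, 17.7-fold and 20.8-fold more. TAS1C (AT2G39675) was 7.56-fold higher in library 2, while TAS2 (AT2G39681) was 5.06-fold and TAS1B (AT1G50055) 1.71-fold higher in library 1. Over tags with 1 match alone TAS1B was 2.99-fold higher in library 1, from 3694 and 4825 counts. The siRNA from TAS3 that targets auxin response factors, TTCTTGACCTTGTAAGACCCC, had 3374 counts in library 2 and was unlisted in library 1. TAS3B (AT5G49615) was unlisted in library 1 and had 38 counts in library 2, 0 of them from tags with 1 match, so none can be given to this locus alone; no tag of TAS3C (AT5G57735) or TAS4 (AT3G25795) was listed in either library.

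Over the 5 loci with enough reads, the fullest register held 73.0% of 21-nt reads in library 1 and 70.1% in library 2, a mean of 71.5% ± 2.05 (SD, n = 2). Random registers of the same tags had medians of 69.6% and 50.8% (permutation p = 0.046 and 0.0001), a test added after the values were seen. Of 10 tests, 7 passed an adjusted p of 0.05 in the permutation test of registers. TAS1A was phased in both libraries, in the same register, with 69.5% and 89.4% of reads and a p of 0.0001 in each, the smallest the permutations can give; random registers had medians of 29.5% and 69.0%, and 1 tag held 25.2% and 50.4% of its counts. TAS2 had its fullest register in common too, with 76.9% in library 1 (permutation p = 0.0918, adjusted p = 0.102), where 1 tag held 62.3% of its counts, and 50.7% in library 2 (permutation p = 0.0002, adjusted p = 0.0005), against random medians of 75.8% and 31.9%. TAS3A also shared its register, with 49.8% in library 1 (permutation p = 0.0897, adjusted p = 0.102) and 49.0% in library 2 (permutation p = 0.021, adjusted p = 0.0301), against random medians of 40.5% and 27.2%. For TAS1C the fullest registers lay 1 nt apart, with 66.0% in library 1 (permutation p = 0.0008, adjusted p = 0.0016) and 60.7% in library 2 (permutation p = 0.0211, adjusted p = 0.0301), against random medians of 30.2% and 45.9%. For TAS1B the share was 55.4% in library 1 (permutation p = 0.376, adjusted p = 0.376) against a random median of 54.8%, so its register there cannot be compared with that of library 2, which held 85.0% (permutation p = 0.0001, adjusted p = 0.000333) against 48.1%. Counted once per distinct tag, the share was 24.7% in library 1 and 16.4% in library 2, where random registers had medians of 13.7% and 9.82% (permutation p = 0.0001 in each).

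The fourth comparison was of the most abundant tags and the protein-coding genes that give small RNAs. Of the 10 most abundant tags, 8 came from MIRNA genes and 2 were 5' fragments of tRNA-Ala, GGGGATGTAGCTCAGATGGTAGA at 2.13% of library 1 and 0.224% of library 2 and GGGGATGTAGCTCAGATGGT at 1.28% and 0.0655%. Besides the mature sequences of miR167a, miR157a, miR159a, miR161.1, miR168a and miR159b, they held TTGAAAGTGACTACATCGGGG, which starts 1 nt before miR161.1 (chromosome 1, 17825730 to 17825750) and took 7.57% of library 1 and 0.554% of library 2. The last was TTGACAGAAGAGAGTGAGCAC from MIR156d (chromosome 5, 3456713 to 3456733), at 0.0619% and 1.85%.

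Of the 10 protein-coding genes with the most reads, AT5G10946, AT5G03553, AT2G47020 and AT1G12290 overlap MIR156d, MIR822, MIR408 and MIR472, and at least 91.2% of their reads lay in those MIRNA genes, so these values cannot be given to the coding genes alone. Within 2 nt of a mature product of either arm lay 100% of the reads of AT5G10946 in both libraries, 77.5% and 94.8% for AT5G03553 and 100% and 98.6% for AT2G47020. For AT1G12290 it was 2.93% of 205 reads in library 1 and 73.8% of 2237 in library 2, where miR472-5p had 1613 and miR472-3p 39, so most of its reads in library 1 were not of the mature miRNA. AT1G63150, a PPR gene, had 1022 CPM in library 1, mostly 21 nt long and 15.5% in sense, and 58.9 in library 2, 88.0% in sense. AT1G63130, another PPR gene, which overlaps MIR5652, had 118 and 349 CPM. AT5G38850, of the TIR-NBS-LRR class of disease resistance genes, had 281 and 766, of which 76.8% and 86.1% were 21 nt long. AT3G20690 had 106 and 397, and 100% and 95.2% of its reads were 24 nt long. The plastid genes psbA and rbcL, for photosystem II protein D1 and the large subunit of Rubisco, had 1006 and 467 in library 1 and 61.9 and 6.10 in library 2, at least 99.1% in sense.

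The last comparison was of where uniquely matching 24-nt reads lie on the chromosomes. Pericentromeres had 883 reads per Mb and arms 490 in library 1, a ratio of 1.80, and 10567 and 6755 in library 2, a ratio of 1.56, for a mean of 1.68 ± 0.168 (SD, n = 2). Within 2 Mb of the midpoints the ratio was 1.18 in library 1 and 0.988 in library 2, so that library 2 had no excess there, and with tags of several matches split over them it was 2.48 and 2.02. Counting each distinct tag once turned the order, to 1.99 in library 1 and 2.04 in library 2.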

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

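The tests of the hairpin arms, of adapter sequence with N calls, of single base differences and of RNA from another organism, and the resampling of tags that gives the intervals below, were chosen after the results had been seen. Some kinds of tag outside the comparisons above stood out by their amount. In library 2, tags with a base call of N held 12.0% of the counts, adapter-like tags 5.60%, and tags with no N, no adapter sequence and no match with up to 1 mismatch 11.7%. In library 1, tags that end as a mature tRNA does, with a CCA absent from the genome, held 0.948%. The corresponding shares in the other library were 0.171%, 0.0127%, 3.90% and 0.0509%.

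The miRNA profile differs between the libraries although the labels give 1 RNA isolation. Counting error with the minimum of 5 counts is argued against. The chi-square over its degrees of freedom was 1.13 between 2 thinnings of library 2 to the total of library 1, and 22221 between the libraries. By the exact test the thinnings gave 0 calls among 44 tested miRNAs, with 1 unadjusted p under 0.05, against 44 calls between the libraries. That test allows for counting error, so few calls were likely from the outset. Both draws were also thinned to 1 total, whereas the listed miRNA totals were 222308 and 1277408. Different amounts of the precursors would move both arms of a hairpin together. Over 16 hairpins the arms' log2 ratios had a correlation of -0.18 (bootstrap interval -0.58 to 0.23, permutation p = 0.497). This does not decide, since some arm sequences come from several MIRNA genes, 7 for miR166a and 3 for miR157a. Their counts sum several precursors. Some arms also lay near the minimum of 5 counts, such as the 5' arm of MIR166a with 5 in each library. Capture that depends on the sequence of each molecule stays open: the arms' ratios differed by a median of 3.77 log2 units (1.57 to 5.97), but random pairs of arms from different hairpins also differed by 3.03 (5th to 95th percentile 1.84 to 4.07), as any profiles not linked by hairpin would. Precursor amounts were the 1 biological explanation tested, and over the 16 hairpins that test did not decide. Reads with 1 match cover single hairpins. For library 1 and 2, the 5' arms had 998 and 115823 for MIR156d, 44 and 6303 for MIR822 and 17 and 3137 for MIR408. The 3' arms had 127 and 97, 142 and 6, and 78 and 199. In shares, each 5' arm was higher in library 2 and each 3' arm in library 1. At these hairpins this argues against precursor amounts alone. Both arms of MIR391 and MIR472 were higher in library 2, miR472-3p with 0 and 39. Whether both files hold the same RNA was not tested, so a difference between RNAs stays open.

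The 24-nt share is lower in library 1 by 19.95 percentage points. Thinning library 2 to the total of library 1 left 16.0 points, 80.4% of the gap (64.3 to 89.4). Leaving out rRNA and tRNA left 18.7 points, 93.6% (52.3 to 111). Neither correction alone removed over 50% of the gap. The total matched is that of the listed tags and not the depth of sequencing, which is not known. A larger difference in depth than the one matched therefore stays open. Both together left 14.4 points, 72.3% of the gap, but with an interval of 16.6 to 93.1 that does not decide. The thinning matched totals that include rRNA and tRNA, so it did not match the counts left without them. No biological explanation was tested.

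A smaller share of the counts of library 2 matches the genome, with a gap of 19.9 points in the unmatched share. Single base differences leave 17.3 points when 1 mismatch is allowed, which argues against them as the main cause. Tags with an N entered this matching, where an N can count as the mismatch. The value therefore overlaps with the next one. Without adapter-like tags and tags with an N the gap was 8.45 points, 42.4% of it (17.5 to 54.7), an interval that reaches past 50%. Tags with an N cannot match exactly, and adapter-like tags have no match by definition. Leaving them out can only remove unmatched counts, so the fall gives their amount and does not test a cause. RNA of another organism stays open for the 11.7% left, since no other genome was used here.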

How the results depend on the processing

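The alternatives with thinning, extended rRNA, N and adapter sequence left out, all annotated miRNAs, unlisted tags at 0, TAS loci by tags with 1 match or target groups with isomiRs were chosen after the data were seen. Values are means of both libraries, and a move is judged against the SD of the 2 libraries, which is wide for most results, so staying within it shows no stability. Between the libraries, 8 of 70 alternative values turned the direction, those of the 21-nt share to library 2 higher by 1.82 points among matching tags and 3.56 points with library 2 thinned. The others were, for library 1 and library 2 among tags with 1 match, MIRNA genes at 65.8% and 20.6%, plastid at 3.12% and 1.26% and other annotated genes at 2.39% and 5.19%; other annotated genes with extended rRNA at 3.63% and 4.47%; the mitochondrion with tags split evenly at 0.367% and 0.171%; and the pericentromere ratio over distinct tags at 1.99 and 2.04. A minimum of 2 counts and a denominator of all lengths change nothing, since every tag has at least 5 counts and 18 to 24 nt. Extended rRNA left the shares of tRNA, snRNA or snoRNA, MIRNA genes, TAS loci, plastid and mitochondrion as they were. Such unchanged values are among the 70, so 8 of 70 is no measure of stability. Counting each distinct tag once gave 12.1% for the 21-nt share, 46.2% for the 24-nt share, 32.5% for the T share of 21-nt reads, 20.5% for the phased share and 2.01 for the pericentromere ratio. The 21-nt share was 37.1% of tags that match the genome, 40.9% without rRNA and tRNA, 46.7% without extended rRNA and tRNA, 37.4% with library 2 thinned, 49.0% with both and 34.8% without N and adapter tags. Listed miRNAs were 22.8% of matching counts and 23.3% with isomiRs. Among tags with 1 match, which leaves out repeated genes by construction, rRNA was 0.481%, MIRNA genes 43.2%, TAS loci 6.94%, plastid 2.19% and intergenic 35.7%. A register of plus or minus 1 nt gave a phased share of 87.9%. The pericentromere ratio was 2.25 with multiple matches split and 1.09 within 2 Mb, where library 1 had 1.18 and library 2, with no excess, 0.988. The 44 miRNA calls became 39 to 48 under 6 settings and 84 of 115 over all annotated miRNAs, a larger set by construction. With quasi-Poisson dispersion, estimated from the same differences that were tested, 0 were called. Calls lost were miR823 and miR824 under both other scalings, miR158b and miR824 with isomiRs, and miR159c, miR319c, miR395a, miR397b and miR775, left untested by a minimum of 50 counts. Otherwise the cause was not tested. Leaving out a library leaves the value of the other: 35.2% to 35.6% for 21 nt and 15.3% to 35.3% for 24 nt; the miRNA comparison then has no value. No paired analysis was possible because there is 1 group. Tags under 5 counts are unlisted, which limits what can be said of rare miRNAs.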

Other observations

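All values here were chosen after the data were seen. Within the rRNA and tRNA fragments the libraries did not move together. Plastid 4.5S rRNA gave 6.57% of library 1 and 0.0857% of library 2, 76.6-fold more, and plastid 23S rRNA 4.01% and 0.161%, whereas nuclear 5.8S rRNA, with 21281 and 249308 counts, had the higher share in library 2. Nuclear tRNA-Ala gave 6.04% of library 1 and 0.870% of library 2, while nuclear tRNA-Gly gave 0.0539% and 0.643%, 11.9-fold more in library 2.

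The miR161 locus was read mostly as a shifted form. Exact miR161.1 was 25.3% of the counts within 2 nt of its ends in library 1 and 2.90% in library 2. The overlapping miR161.2, which starts upstream at position 17825722 of chromosome 1, had 571 counts in library 2 and was unlisted in library 1. Of 215 protein-coding genes with at least 10 uniquely matching reads of 20 to 25 nt in each library, 78 had the higher share in library 1 and 137 in library 2.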
